A study of Mus musculus with 12 samples.

How the data were processed

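Total RNA of mouse extraembryonic ectoderm was sequenced in 12 libraries, 3 each of wild type and of Suv39h2 and Prdm2 double knockout tissue at E6.5 and E7.5. Per the labels' protocols, embryos were made by in vitro fertilisation, transferred to foster females and dissected, with Reichert's membrane and the ectoplacental cone removed. Zygotes of the KO groups were injected with Cas9 mRNA and guide RNAs. Libraries were made with the SMARTer Stranded Total RNA-Seq kit with depletion of ribosomal cDNA, per the labels' protocols. The submitters' processing notes name HISAT2 2.1.0, SAMtools 1.7, StringTie 1.3.4, Cufflinks (no version) and the mm10 build. These sources do not state which tool gave the values, which annotation was used or whether the counting used strand. The deposited values are log2 of FPKM + 1, per the file headers, with 1 column per library and no stated normalization between samples. After the log was undone, the deposited FPKM of each library summed to between 511403 and 518105.

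The file holds 24421 rows named by gene symbol, of which 23057 are above 0 in at least 1 library. In 27 rows a date stands in place of a symbol, and 4 rows share a name with another row; 15 of the date rows were tested, and none was named. All 12 value columns were used. Symbols were matched to GENCODE vM21 (mm10) for coordinates, with a match for 96.3% of the tested rows. Genes that share reads with near-identical copies (histones, ribosomal proteins, Rhox genes), overlapping genes and antisense genes are uncertain, since the counting is not stated. Depth is unknown without counts. Relative depth was estimated from the most frequent ratios between low FPKM values of the same genes in pairs of libraries. The method was checked on 6 simulated libraries made of read counts, which give such ratios by design. The estimates were 55.5% to 100% of the deepest library in E6.5 KO and 41.2% to 50.3% in E6.5 WT. They were 32.1% to 36.6% in E7.5 KO and 29.9% to 44.8% in E7.5 WT.

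The deposited log2 values were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, for the 10402 genes with a mean of at least 1 over the 12 libraries. A single fit of the 4 group means, with 8 residual degrees of freedom, gave KO against WT at each stage, E7.5 against E6.5 in each genotype and the interaction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The median SD of a gene within groups was 0.09 and the median standard error of a difference 0.07. Exact permutation tests of single genes used 3 against 3 libraries (2-sided). Gene lists were fixed with the design before the data were examined. Those with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, repeated with an estimated correlation, and with fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes. Counts within a list are given over all genes tested and adjusted over the list alone. The steps were tested on simulated data: for KO against WT at E6.5, with 200 of 10402 genes changed, the fit recovered 37.3% of changes of 0.25, 91.0% of changes of 0.5 and 100% of changes of 1 on the log2 scale, and 10 of 162 calls were false.

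Named genes follow a rule written before the data were examined: for the KO comparisons and the stage comparison in WT, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, up to 4 called members of each list with the largest change, the 5 largest interactions, and always Suv39h2, Prdm2, Xist and the Y-linked genes. Predicted genes, clone names, microRNA and small RNA genes and duplicated symbols were counted but not named, and the text gives part of the genes the rule allows. Differences and means are rounded to 2 decimals, or to 3 where 2 would coincide with a setting or a version number in the scripts. Other settings tried, as laid down beforehand, were no filter, a filter of 2, a pseudocount of 0.1, rescaling to TPM, quantile normalization, only the 6 libraries compared, the replicate number as a block, a robust variance model, array weights, each library left out in turn, and for the overlap an unadjusted threshold. Leaving out Rn45s with rescaling, subtracting the mean FPKM of olfactory receptor genes, leaving out chromosomes X and Y, and the alternatives for the stage and interaction values of single genes were added after seeing the data. Other computations and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.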

Results

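Total RNA of mouse extraembryonic ectoderm (ExE), the trophoblast tissue next to the epiblast of the early embryo, was measured in 12 libraries. They form 4 groups of 3 replicates: wild type (WT) and double knockout (KO) of the genes Suv39h2 and Prdm2, at embryonic days E6.5 and E7.5. Per the labels, eggs of C57BL/6N females were fertilised in vitro with sperm of PWK/PhJ males, and Cas9 mRNA with guide RNAs was injected into the zygotes of the KO groups. Values are deposited as log2(FPKM + 1), and every difference given here is a difference on that scale. Read counts were not used here, so the absolute depth is unknown. The FPKM values of a library sum to between 511403 and 518105. Ratios between low values of the same genes put the estimated depths between 29.9% and 100% of the deepest library, E6.5 KO replicate 1. The ribosomal precursor Rn45s held 9.65% ± 0.410 (SD, n = 3) of the FPKM total in E6.5 WT, 8.46% ± 0.376 in E6.5 KO, 27.7% ± 2.41 in E7.5 WT and 23.4% ± 0.947 in E7.5 KO. Across genes, libraries of the same group correlated at 0.992 to 0.995 and libraries of different groups at 0.964 to 0.989. The labels do not say that replicates are separate animals or pools, so the p-values measure only the spread between these samples.

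The 2 targeted genes, which both encode methyltransferases of histone H3 lysine 9 (H3K9), were still transcribed in every library labelled KO. Suv39h2 (mm10, chromosome 2, positions 3455815 to 3475031) stood at 4.17, 4.08 and 3.97 in the KO libraries and 4.48, 4.45 and 4.47 in the WT libraries at E6.5, a difference of -0.39 (SE 0.05, adjusted p = 0.000646) to 75.4% of the WT FPKM. At E7.5 its KO libraries stood at 4.51, 4.49 and 4.58 and its WT libraries at 4.49, 4.61 and 4.54, a difference of -0.02 (SE 0.05, adjusted p = 0.801). Prdm2 (chromosome 4, positions 143107391 to 143212995) stood at 6.30, 6.35 and 6.29 in KO and 6.26, 6.23 and 6.25 in WT at E6.5, a difference of 0.07 (SE 0.05, adjusted p = 0.418). At E7.5 it stood at 6.19, 6.10 and 6.14 in KO and 6.04, 6.17 and 5.97 in WT, a difference of 0.09 (SE 0.05, adjusted p = 0.171). The 2-sided exact permutation p was 0.1, 0.6, 0.1 and 0.3 in the same order, and 0.1 is the smallest that 3 against 3 libraries allow. Values per whole gene do not show small deletions or insertions, so they do not check the edits, and KO and WT name the libraries as labelled throughout. After quantile normalization Suv39h2 at E7.5 was -0.13 (adjusted p = 0.0494), and without E7.5 WT replicate 2 the Prdm2 difference at E7.5 was 0.14 (adjusted p = 0.0169).

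**Figure D1:**
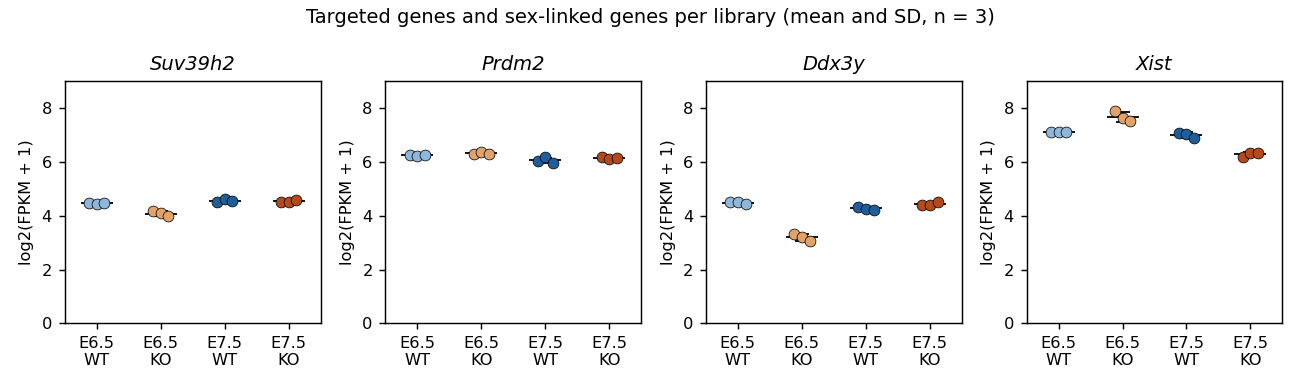
Level of Suv39h2, Prdm2, Ddx3y and Xist in log2(FPKM + 1) (vertical axis) by group (horizontal axis), with 1 point per library, a line at the mean and bars for the SD of the 3. Suv39h2 and Ddx3y are lower in the E6.5 KO libraries than in E6.5 WT, and Xist is higher there and lower in E7.5 KO than in E7.5 WT.

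At E6.5 the comparison of KO with WT asks which transcripts of the tissue differ when both enzymes are targeted. The group labels name no injection control, so effects of the injection cannot be told apart from those of the KO at either stage. Genes of the visceral endoderm, the epithelium that covers the epiblast and ExE, stood far higher in KO. Apob, the backbone protein of lipoprotein particles (chromosome 12, positions 7977648 to 8016835), was 0.17 ± 0.06 in WT and 6.54 ± 0.06 in KO (SD, n = 3), a rise of 6.37 (SE 0.18, adjusted p = 3.5e-10). Cubn, an endocytic receptor (chromosome 2, positions 13276338 to 13491813), was 0.36 ± 0.07 and 6.44 ± 0.07, a rise of 6.08 (SE 0.07, adjusted p = 2.0e-13), and Lrp2, its partner receptor, rose by 4.35 (SE 0.10). The apolipoproteins Apoa1 (3.44) and Apoa4 (3.12), the transcription factor Hnf4a (3.33) and the endocytic adaptor Dab2 (3.15) rose as well, and Apoa4 is listed at 0 in the WT libraries. Of the visceral endoderm genes, 11 of 12 tested genes rose (11 rose adjusted over the list alone), with a median of 3.13. For visceral endoderm genes camera gave an adjusted p = 4.1e-31, or an adjusted p = 4.9e-05 with an estimated correlation. The member that did not pass was Rhox5. Counting the members below the expression filter, 21 of 22 listed genes had all 3 KO libraries above all 3 WT libraries. Chance gives 5% in this direction for a single gene, and 34.4% of all tested genes showed no overlap in either direction.

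The largest other rises at E6.5 were in the membrane peptidase Dpp4, 4.74 (SE 0.21), which is listed at 0 in the WT libraries, the heparan sulfate proteoglycan Gpc3, 3.72 (SE 0.05), and the hyaluronan synthase Has2, 3.07 (SE 0.18). Genes of the parietal endoderm, which lays down the basement membrane around the embryo, were higher too: 7 of 9 tested genes rose (8 rose adjusted over the list alone), with Lama1 (3.01), Col4a1 (2.28), Col4a2 (1.48) and the collagen chaperone Serpinh1 (1.23). For parietal endoderm genes camera gave an adjusted p = 6.1e-10, or an adjusted p = 0.00245 with an estimated correlation. Of the epiblast genes, 5 of 8 tested genes rose (7 rose and 1 fell adjusted over the list alone), led by the Nodal coreceptor Tdgf1 (1.13) and the pluripotency factor Pou5f1 (1.12). For epiblast genes camera gave an adjusted p = 0.000168, or an adjusted p = 0.0164 with an estimated correlation. Of the extraembryonic mesoderm and blood progenitor genes, 4 of 10 tested genes rose (5 rose adjusted over the list alone), among them the endothelial cadherin Cdh5 (1.10), Lmo2 (0.57) and Runx1 (0.42). For extraembryonic mesoderm and blood progenitor genes camera gave an adjusted p = 0.0186, or an adjusted p = 0.149 with an estimated correlation; without WT replicate 1 the adjusted p was 0.0881. Of 4 tested primitive streak and mesoderm genes, only Pdgfra (1.79) rose (2 rose adjusted over the list alone). Of the 2 tested trophoblast giant cell genes, Hand1 (0.47) rose (2 adjusted over the list alone).

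Many immediate early genes and FGF and ERK target genes (8 and 6 of them after quantile normalization) rose at E6.5, in the same libraries as the endoderm markers. Of the immediate early genes, 10 of 14 tested genes rose (10 rose adjusted over the list alone), with Egr1 (0.75), Jun (0.74), Zfp36 (0.74) and Junb (0.68). For immediate early genes camera gave an adjusted p = 6.9e-08, or an adjusted p = 0.0146 with an estimated correlation. Of the FGF and ERK target genes, 9 of 13 tested genes rose (10 rose adjusted over the list alone), among them the phosphatase Dusp4 (0.82), Phlda1 (0.74) and the feedback inhibitor Spry2 (0.53). For FGF and ERK target genes camera gave an adjusted p = 3.4e-06, or an adjusted p = 0.0239 with an estimated correlation. Of the BMP and SMAD target genes, 4 of 9 tested genes rose (5 rose adjusted over the list alone), led by the homeobox gene Msx1 (0.94); after quantile normalization 1 rose. For BMP and SMAD target genes camera gave an adjusted p = 0.00291, or an adjusted p = 0.0395 with an estimated correlation. Of the cholesterol synthesis genes, 7 of 19 tested genes rose (12 rose adjusted over the list alone), with Stard4 (0.37), the regulator Srebf2 (0.31) and Fdps (0.31). For cholesterol synthesis genes camera gave an adjusted p = 5.1e-05, or an adjusted p = 0.0164 with an estimated correlation. Of the WNT target genes, 1 of 5 tested genes rose (1 rose adjusted over the list alone), which was Nkd1 (0.53). For WNT target genes camera gave an adjusted p = 0.439, or an adjusted p = 0.605 with an estimated correlation.

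Fewer genes fell at E6.5, among them Klhl13 (-0.96) and the noncoding RNA Lincenc1 (-0.73). Of the p53 target genes, 5 of 16 tested genes fell (5 fell adjusted over the list alone), with Plk2 (-1.08), Trp53inp1 (-0.47), the cell death gene Pmaip1 (-0.43) and Ccng1 (-0.27). For p53 target genes camera gave an adjusted p = 9.7e-07, or an adjusted p = 0.00485 with an estimated correlation. Ccng1 did not pass with any library but KO replicate 2 left out (limma adjusted p = 0.0545 to 0.107). Of the replication-dependent histone genes, 3 of 66 tested genes rose and 8 fell (3 rose and 11 fell adjusted over the list alone). For replication-dependent histone genes camera gave an adjusted p = 2.0e-07, or an adjusted p = 0.0395 with an estimated correlation; histone genes are near-identical copies, so single values are uncertain. Of the hypoxia and glycolysis genes, 1 of 18 tested genes rose and 5 fell (1 rose and 5 fell adjusted over the list alone), with Bnip3 (-0.41) lower and Vegfa (0.34) higher. For hypoxia and glycolysis genes camera gave an adjusted p = 0.000168, or an adjusted p = 0.169 with an estimated correlation; the latter was 0.00628 with Rn45s left out. Of the germline genes, 2 of 11 tested genes fell (2 fell adjusted over the list alone), namely Tex15 (-0.57) and Mov10l1 (-0.46). Mov10l1 did not pass without KO replicate 1 or 3 or without WT replicate 1 or 2 (limma adjusted p = 0.0563 to 0.0670). For germline genes camera gave an adjusted p = 0.0125, or an adjusted p = 0.0571 with an estimated correlation. Of the mitosis genes, 1 of 20 tested genes fell (1 fell adjusted over the list alone), which was Top2a (-0.18). With Rn45s left out 4 fell, and after quantile normalization 2 fell. For mitosis genes camera gave an adjusted p = 0.000168, or an adjusted p = 0.296 with an estimated correlation. The Y-linked genes Eif2s3y (-1.42), Ddx3y (-1.28), Kdm5d (-0.90) and Uty (-0.72) all fell (4 fell adjusted over the list alone), to between 22.1% and 38.5% of the WT FPKM. Xist, the RNA that coats the inactive X chromosome in female cells, rose by 0.57 (SE 0.08, adjusted p = 0.00113), from 137 to 205 FPKM. These sex-linked values moved in the same libraries as every gene group of this comparison. A larger share of female tissue in the E6.5 KO libraries would give lower Y-linked and higher Xist values. The sex makeup of the samples was not adjusted for. Its effects cannot be told apart from those of the KO at E6.5 or in the interaction.

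Genes of the ExE itself had a median difference of 0.12 at E6.5. Of 26, 15 had all 3 KO libraries above all 3 WT libraries and 1 had all below. Of the ExE and trophoblast stem cell genes, 8 of 26 tested genes rose (8 rose and 1 fell adjusted over the list alone), with Gata3 (0.59) and Tead4 (0.42) highest among them. For ExE and trophoblast stem cell genes camera gave an adjusted p = 0.00291, or an adjusted p = 0.198 with an estimated correlation; the latter was 0.0216 with Rn45s left out. Of the ectoplacental cone and spongiotrophoblast genes, 1 of 10 tested genes rose and 3 fell (2 rose and 3 fell adjusted over the list alone), with Plac1 (-0.29) lower, which did not pass with any library of the comparison but KO replicate 2 left out (limma adjusted p = 0.0559 to 0.0853). For ectoplacental cone and spongiotrophoblast genes camera gave an adjusted p = 0.283, or an adjusted p = 0.580 with an estimated correlation. Of the syncytiotrophoblast and labyrinth genes, 2 of 11 tested genes rose and 3 fell (2 rose and 3 fell adjusted over the list alone), with Dlx3 (-0.65) and the transferrin receptor Tfrc (-0.31) lower. For syncytiotrophoblast and labyrinth genes camera gave an adjusted p = 0.0449, or an adjusted p = 0.344 with an estimated correlation. That list had an adjusted p = 0.0821 without KO replicate 1 and 0.0856 without WT replicate 1, and the H3K9 demethylases 0.0446 without WT replicate 1. Among chromatin lists, 3 and 2 of 21 tested H3K9 methyltransferases and readers rose and fell (3 and 2 adjusted over the list alone), with Atf7ip (-0.28) and Atrx (0.19). For H3K9 methyltransferases and readers camera gave an adjusted p = 0.613, or an adjusted p = 0.836 with an estimated correlation. Of the DNA methylation and demethylation genes, 4 of 15 tested genes rose and 1 fell (4 rose and 2 fell adjusted over the list alone), led by Dnmt3a (0.48). For DNA methylation and demethylation genes camera gave an adjusted p = 0.833, or an adjusted p = 0.899 with an estimated correlation. Of the Polycomb genes, 2 of 21 tested genes rose (3 rose adjusted over the list alone). For Polycomb genes camera gave an adjusted p = 0.474, or an adjusted p = 0.768 with an estimated correlation. limma called 0 of the 10 H3K9 demethylases, with 0 at an unadjusted p under 0.05 and a fry adjusted p = 0.346, and 0 of the 13 Rhox genes, with 1 at an unadjusted p under 0.05 and a fry adjusted p = 0.937. The maternally expressed imprinted RNAs Meg3 (0.69) and Rian (0.40) rose; of the 15 tested genes of their list 2 rose and 2 fell (4 rose and 4 fell adjusted over the list alone), and camera gave that list an adjusted p = 0.412.

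The other lists with at least 5 tested genes at E6.5 had adjusted camera p-values of 0.672 (interferon response, 1 of 5 rose), 0.780 (paternally expressed imprinted, 1 rose and 1 fell of 21), 0.613 (DNA replication, 2 rose and 1 fell of 20), 0.584 (unfolded protein and amino acid response, 2 rose of 16), 0.780 (ribosomal proteins, 8 rose and 2 fell of 78) and 0.225 (Zfp zinc fingers, 8 rose and 7 fell of 252). Adjusted over the list alone, these counts were 1 in interferon response, 3 and 3 in paternally expressed imprinted, 2 and 1 in DNA replication, 2 in unfolded protein, 8 and 2 in ribosomal proteins and 8 and 4 in Zfp genes. The medians of the methyltransferase, DNA methylation, Polycomb, interferon, paternally imprinted, DNA replication, WNT and Zfp lists at E6.5 changed sign after quantile normalization. Rises and falls were then 1 and 3 for methyltransferases and 5 and 14 for Zfp genes.

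In all, limma called 1070 of 10402 tested genes at E6.5 (adjusted p under 0.05), of which 827 rose and 243 fell; 52 rose and 5 fell by more than 1. Among called genes 99.8% showed no overlap between the 3 KO and the 3 WT libraries, against 34.4% of all tested genes and 10% by chance. Of 29 lists tested, camera called 15, and 9 of them with an estimated correlation. Rises made up 77.3% of the calls as deposited, 65.8% (731 rose, 380 fell) with Rn45s left out and the rest rescaled, and 50.5% (504 rose, 494 fell) after quantile normalization. The count was 625 without KO replicate 1, 582 without KO replicate 2, 665, 662 and 676 without WT replicates 1, 2 and 3, and 2198 with libraries weighted by their spread.

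At E7.5 the same comparison found genes of the epiblast and of early mesoderm higher in KO. T (brachyury), the transcription factor that marks the primitive streak, was 1.12 ± 0.02 in WT and 5.02 ± 0.12 in KO (SD, n = 3), a rise of 3.91 (SE 0.11, adjusted p = 4.9e-10). The VEGF receptor Kdr (chromosome 5, positions 75932827 to 75978458), carried by blood and vessel progenitors, was 1.07 ± 0.12 and 3.77 ± 0.05, a rise of 2.70 (SE 0.08, adjusted p = 8.6e-10), and the mesoderm factor Foxf1 rose by 2.62 (SE 0.12). All 4 tested primitive streak and mesoderm genes rose (4 adjusted over the list alone), Snai1 (1.14) and Pdgfra (0.69) among them, with a median of 1.88. Of the epiblast genes, 7 of 8 tested genes rose (7 rose adjusted over the list alone), with Tdgf1 (2.495), Pou5f1 (2.39) and Sox3 (1.40). For epiblast genes camera gave an adjusted p = 3.6e-06, or an adjusted p = 0.0107 with an estimated correlation. Of the extraembryonic mesoderm and blood progenitor genes, 8 of 10 tested genes rose (9 rose adjusted over the list alone), with the embryonic globin Hbb-bh1 (2.14), Lmo2 (1.74) and Etv2 (1.36). For extraembryonic mesoderm and blood progenitor genes camera gave an adjusted p = 0.000524, or an adjusted p = 0.0516 with an estimated correlation; the latter was 0.0293 with Rn45s left out. Members below the filter were counted too. All 3 KO libraries stood above all 3 WT libraries for 14 of 17 epiblast, 14 of 17 streak and 15 of 18 extraembryonic mesoderm genes. Chance gives 5% for a single gene, but 46.9% of all tested genes showed no overlap in either direction at E7.5, and most called genes rose.

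Further large rises at E7.5 were in Gpc3, 2.63 (SE 0.05), the junction regulator Amot, 2.62 (SE 0.05), the gap junction protein Gja1, 2.41 (SE 0.07), and Armcx4, 2.34 (SE 0.11). Rps28 rose by 2.495 (SE 0.24), but ribosomal protein genes have near-identical copies that share reads, so that value is uncertain. Of the FGF and ERK target genes, 12 of 13 tested genes rose (12 rose adjusted over the list alone), with Dusp6 (2.15), Il17rd (2.14) and Spry4 (1.68), which act back on the pathway that induces them. For FGF and ERK target genes camera gave an adjusted p = 9.1e-09, or an adjusted p = 0.0107 with an estimated correlation. Of the WNT target genes, 5 of 5 tested genes rose (5 rose adjusted over the list alone), including Axin2 (1.10) and Apcdd1 (0.95). For WNT target genes camera gave an adjusted p = 0.00322, or an adjusted p = 0.0726 with an estimated correlation; the latter was 0.0309 with Rn45s left out, and 3 genes rose after quantile normalization. Of the BMP and SMAD target genes, 5 of 9 tested genes rose and 2 fell (5 rose and 2 fell adjusted over the list alone), with Msx1 (2.24) and Bambi (1.05) higher and Id1 (-0.67) lower. For BMP and SMAD target genes camera gave an adjusted p = 0.854, or an adjusted p = 0.892 with an estimated correlation. Of the cholesterol synthesis genes, 17 of 19 tested genes rose (17 rose adjusted over the list alone), with Srebf2 (0.79), Msmo1 (0.77) and Lss (0.70). For cholesterol synthesis genes camera gave an adjusted p = 2.5e-06, or an adjusted p = 0.0107 with an estimated correlation. Of the parietal endoderm genes, 7 of 9 tested genes rose (7 rose adjusted over the list alone), with Pth1r (1.32) and Col4a1 (0.93). For parietal endoderm genes camera gave an adjusted p = 0.000849, or an adjusted p = 0.0362 with an estimated correlation. Of the visceral endoderm genes, 7 of 12 tested genes rose and 1 fell (8 rose and 1 fell adjusted over the list alone), with Gata4 (1.69) far above Cubn (0.47) and Lrp2 (0.47). For visceral endoderm genes camera gave an adjusted p = 0.157, or an adjusted p = 0.255 with an estimated correlation.

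Several homeobox genes of the Rhox cluster on chromosome X, expressed in trophoblast and germ cells, fell at E7.5. Rhox9 (chromosome X, positions 37899097 to 37901770) was 4.40 ± 0.09 in WT and 2.44 ± 0.01 in KO (SD, n = 3), a difference of -1.96 (SE 0.07, adjusted p = 2.4e-09), and Rhox6 fell by 1.91. Of the Rhox genes, 1 of 13 tested genes rose and 7 fell (2 rose and 7 fell adjusted over the list alone). For Rhox genes camera gave an adjusted p = 1.1e-05, or an adjusted p = 0.0107 with an estimated correlation; Rhox4b and Rhox4d are near-identical copies whose values are uncertain. Other falls were in the trophoblast homeobox gene Esx1 (-1.53), the integrin Itga4 (-1.27), Irx4 (-1.19), the trophoblast factor Gata2 (-1.05) and the smooth muscle actin Acta2 (-1.04). Cebpb had a difference of -2.74 (SE 1.01, adjusted p = 0.0488), but libraries of 1 group differ in it by several log2 units, and it did not pass with any library of the comparison but KO replicate 3 left out (limma adjusted p = 0.0866 to 0.163). Of the ExE and trophoblast stem cell genes, 16 of 26 tested genes rose and 4 fell (17 rose and 4 fell adjusted over the list alone), with the signal Bmp4 (1.82) and Zic3 (1.81) against the falls of Rhox6, Rhox9 and Gata2. For ExE and trophoblast stem cell genes camera gave an adjusted p = 0.137, or an adjusted p = 0.598 with an estimated correlation. With Rn45s left out 12 of them rose and 7 fell, and after quantile normalization 13 rose and 5 fell. Of the ectoplacental cone and spongiotrophoblast genes, 7 of 10 tested genes rose and 2 fell (8 rose and 2 fell adjusted over the list alone), with Plac1 (1.46) and Nrk (0.77) higher and Peg10 (-0.53) lower. For ectoplacental cone and spongiotrophoblast genes camera gave an adjusted p = 0.219, or an adjusted p = 0.598 with an estimated correlation. Of the syncytiotrophoblast and labyrinth genes, 5 of 11 tested genes rose (7 rose adjusted over the list alone), with Lifr (0.92) and Cebpa (0.75). For syncytiotrophoblast and labyrinth genes camera gave an adjusted p = 0.0537, or an adjusted p = 0.410 with an estimated correlation; without E7.5 WT replicate 1 the adjusted p was 0.0310. Of the 2 tested giant cell genes Hand1 (-0.17) fell (1 adjusted over the list alone).

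Ribosomal protein and histone genes were higher in E7.5 KO: 48 of 78 tested genes rose and 3 fell (51 rose and 3 fell adjusted over the list alone) among ribosomal protein genes, and 43 of 66 tested genes rose and 1 fell (43 rose and 1 fell adjusted over the list alone) among histone genes. For ribosomal protein genes camera gave an adjusted p = 5.4e-05, or an adjusted p = 0.0650 with an estimated correlation. For replication-dependent histone genes camera gave an adjusted p = 5.4e-05, or an adjusted p = 0.0981 with an estimated correlation. With Rn45s, whose share was lower in KO, left out, 38 ribosomal protein genes rose and 6 fell (camera adjusted p = 0.00154, or 0.224 with an estimated correlation, median 0.12 against 0.20 as deposited), and 33 histone genes rose and 1 fell (camera adjusted p = 4.8e-05, or 0.116, median 0.22 against 0.29). Of the germline genes, 3 of 11 tested genes fell (2 fell adjusted over the list alone). For germline genes camera gave an adjusted p = 0.00645, or an adjusted p = 0.0516 with an estimated correlation. Among imprinted genes, Mest (1.51), Rian (1.19), Meg3 (1.12), Rtl1 (1.19) and Dlk1 (0.94) rose; in the maternal list 7 of 15 tested genes rose and 4 fell (8 rose and 4 fell adjusted over the list alone), and in the paternal list 10 of 21 tested genes rose and 5 fell (12 rose and 5 fell adjusted over the list alone). Camera's adjusted p-values for them were 0.877 and 0.877. Of the H3K9 methyltransferases and readers, 11 of 21 tested genes rose and 1 fell (11 rose and 1 fell adjusted over the list alone), with Suv39h1 (0.66), the paralog of the targeted enzyme, and Atrx (0.55). For H3K9 methyltransferases and readers camera gave an adjusted p = 0.191, or an adjusted p = 0.725 with an estimated correlation. Of the H3K9 demethylases, 6 of 10 tested genes rose (6 rose adjusted over the list alone), led by Kdm7a (1.26). For H3K9 demethylases camera gave an adjusted p = 0.271, or an adjusted p = 0.700 with an estimated correlation. Of the demethylases 3 rose and 2 fell after quantile normalization, and 4 and 2 with Rn45s left out. Of the DNA methylation and demethylation genes, 7 of 15 tested genes rose and 3 fell (7 rose and 3 fell adjusted over the list alone), with Dnmt3b (0.65). For DNA methylation and demethylation genes camera gave an adjusted p = 0.877, or an adjusted p = 0.918 with an estimated correlation. Of the Polycomb genes, 9 of 21 tested genes rose and 2 fell (10 rose and 2 fell adjusted over the list alone), with Phf19 (-0.80). For Polycomb genes camera gave an adjusted p = 0.698, or an adjusted p = 0.892 with an estimated correlation. The DNA methylation and paternally imprinted lists had a positive median and a camera direction of down. After quantile normalization rises and falls were 2 and 6 for DNA methylation, 3 and 4 for maternal and 7 and 7 for paternal imprinted genes.

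Xist fell at E7.5 by 0.71 (SE 0.08, adjusted p = 4.3e-05), from 127 to 77.1 FPKM, and of the other tested X inactivation RNAs Ftx fell (-0.40; 3 fell adjusted over the list alone). The Y-linked genes did not pass: Ddx3y 0.15, Eif2s3y -0.09, Kdm5d 0.16 and Uty 0.14, of which Kdm5d and Uty were below 0 after quantile normalization; limma called 0 of 4, with 1 at an unadjusted p under 0.05. The remaining lists had adjusted camera p-values of 0.535 (interferon response, 1 of 5 rose), 0.540 (mitosis, 7 rose and 1 fell of 20), 0.471 (DNA replication, 6 of 20 rose), 0.877 (p53 targets, 5 of 16 rose), 0.492 (hypoxia and glycolysis, 8 rose and 1 fell of 18), 0.780 (immediate early, 7 rose and 3 fell of 14), 0.877 (unfolded protein, 5 rose and 1 fell of 16) and 0.536 (Zfp zinc fingers, 65 rose and 12 fell of 252). Adjusted over the list alone, these counts were 1 in interferon response, 7 and 1 in mitosis, 5 in DNA replication, 4 in p53 targets, 9 and 1 in hypoxia, 8 and 3 in immediate early, 5 and 1 in unfolded protein and 58 and 12 in Zfp genes. The medians of the mitosis, DNA replication, p53, unfolded protein, DNA methylation and Zfp lists changed sign after quantile normalization, and 32 Zfp genes then rose and 56 fell. Rises and falls of mitosis genes were 3 and 6 both after quantile normalization and with Rn45s left out. After quantile normalization they were 2 and 3 for unfolded protein, 3 and 3 for p53 targets, 0 and 2 for interferon response and 5 and 3 for hypoxia. Hypoxia genes had 4 and 2 with Rn45s left out.

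**Figure D2:**
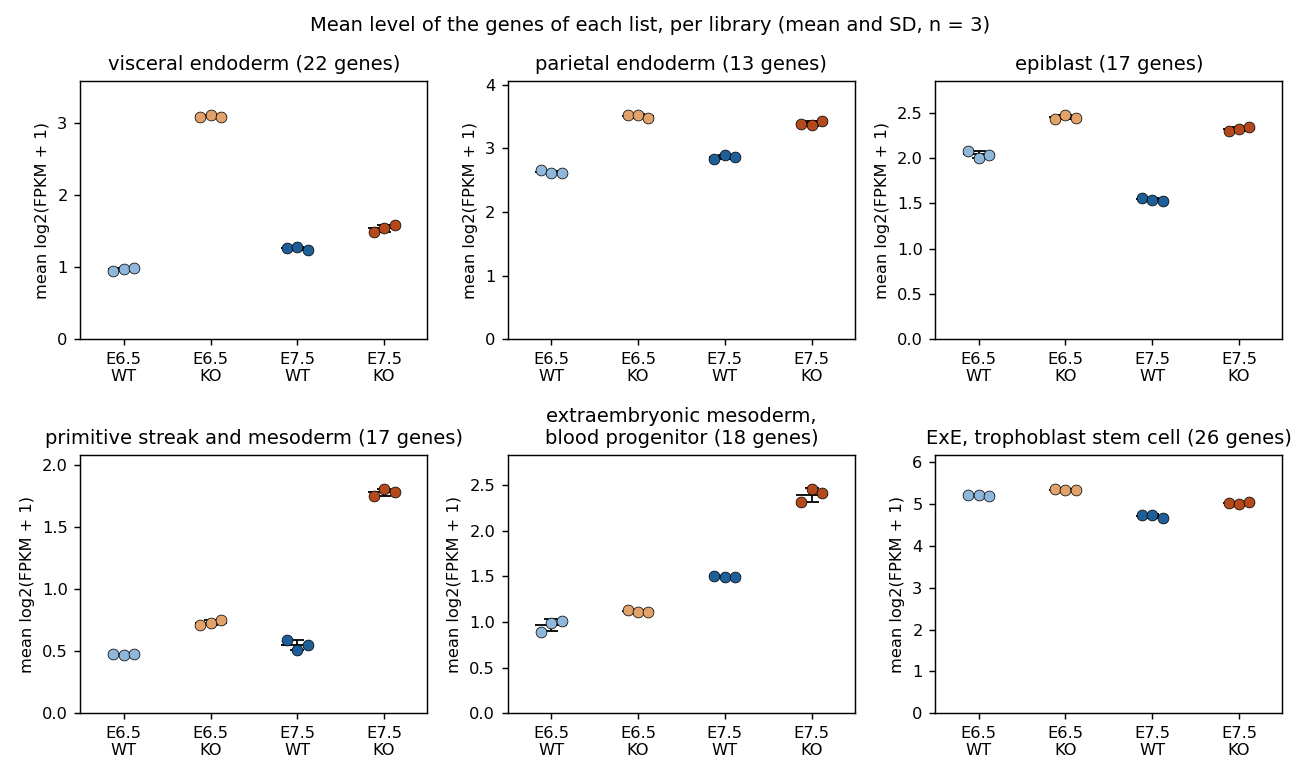
Mean log2(FPKM + 1) of the genes of 6 lists (vertical axes) by group (horizontal axes), with 1 point per library, a line at the mean and bars for the SD of the 3. Visceral endoderm genes stand highest in the 3 E6.5 KO libraries, and epiblast and mesoderm genes in the 3 E7.5 KO libraries stand above E7.5 WT.

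In all, limma called 4085 of 10402 genes at E7.5, of which 3391 rose and 694 fell; 184 rose and 15 fell by more than 1. Among called genes 95.5% showed no overlap between groups, against 46.9% of all tested genes and 10% by chance. Of 29 lists, camera called 10, and 5 of them with an estimated correlation. Rises made up 83.0% of the calls as deposited, 62.2% (2278 rose, 1383 fell) with Rn45s left out, and 44.6% (1725 rose, 2140 fell) after quantile normalization, which moved the median of all genes from 0.11 to -0.03.

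Both stages shared part of their calls: 535 genes rose at both, where independent lists would share 270, and 60 fell at both, where they would share 16.2. Another 108 genes were called in opposite directions, with 134 for independent lists. Gpc3, Amot, Tdgf1 and Pou5f1 rose at both stages, while Apob, Dpp4, Hnf4a and Apoa1 were called at E6.5 and not at E7.5. Across genes, which are not independent replicates, the differences at the 2 stages correlated at 0.23 (Pearson) and 0.27 (Spearman). The comparisons share no library. They do share 1 estimate of the spread per gene, which favours calls of the same genes at both stages. Rn45s also had a lower share in KO at both. With Rn45s left out, the median of all genes went from 0.040 to 0.024 at E6.5 and from 0.105 to 0.035 at E7.5. The numbers for independent lists are therefore no test of the overlap.

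**Figure D3:**
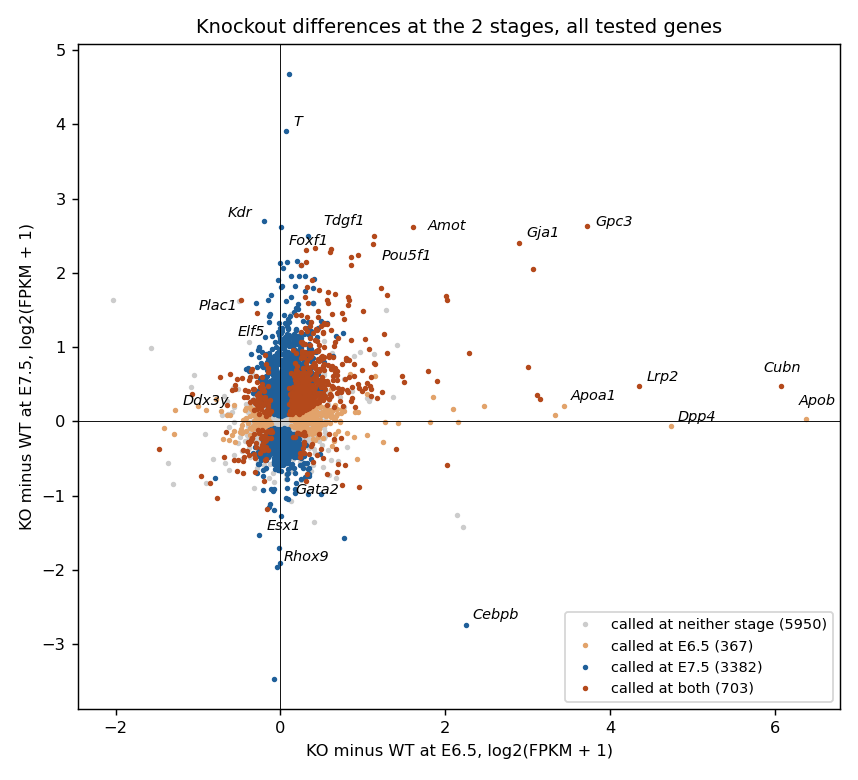
Difference of KO minus WT in log2(FPKM + 1) at E6.5 (horizontal) and E7.5 (vertical) for each of the 10402 tested genes, coloured by the stage at which limma called it. Apob, Cubn and Dpp4 lie far right near 0 on the vertical axis, and T, Kdr and Foxf1 lie high near 0 on the horizontal axis.

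The test of the interaction asks whether the KO difference itself differs between stages, as the difference at E7.5 minus that at E6.5. The 5 largest were Apob -6.34 (SE 0.25, adjusted p = 3.2e-08), Cubn -5.60 (SE 0.11), Dpp4 -4.80 (SE 0.30), Lrp2 -3.88 (SE 0.14) and the erratic Cebpb -4.98 (SE 1.42). Cebpb did not pass with any of 9 of the 12 libraries left out, that is all but E6.5 WT replicate 2, E7.5 KO replicate 3 and E7.5 WT replicate 1 (limma adjusted p = 0.0549 to 0.0686). Of the visceral endoderm genes, 1 of 12 tested genes had a higher and 10 a lower difference at E7.5 (1 and 11 adjusted over the list alone). For visceral endoderm genes camera gave an adjusted p = 1.0e-22, or an adjusted p = 0.000162 with an estimated correlation. Of the epiblast genes, 7 of 8 had a higher difference at E7.5 (7 adjusted over the list alone). For epiblast genes camera gave an adjusted p = 1.3e-05, or an adjusted p = 0.0165 with an estimated correlation. Of the FGF and ERK target genes, 10 of 13 did (10 adjusted over the list alone). For FGF and ERK target genes camera gave an adjusted p = 6.9e-07, or an adjusted p = 0.0213 with an estimated correlation. Parietal endoderm genes had 2 higher and 4 lower of 9 (2 and 4 adjusted over the list alone; adjusted camera p = 0.00279, 0.0450 with an estimated correlation) and Rhox genes 1 higher and 5 lower of 13 (1 and 7 adjusted over the list alone; adjusted camera p = 0.000248, 0.0213 with an estimated correlation). Cholesterol synthesis genes had 10 of 19 higher, ribosomal protein genes 35 higher and 2 lower of 78 and histone genes 38 of 66 higher, against 11, 42 and 2, and 46 adjusted over the list alone, and adjusted p-values with an estimated correlation of 0.0450, 0.0473 and 0.0213. Of the ribosomal protein genes 20 were higher and 2 lower with Rn45s left out, with a median of 0.12 and an adjusted p = 0.140 with an estimated correlation. Suv39h2 had 0.37 (adjusted p = 0.00472).

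In all, limma called 1982 genes for the interaction, 1476 higher and 506 lower at E7.5, and 134 and 63 of them by more than 1. Camera called 15 of 29 lists, 8 of them with an estimated correlation. The calls lost with it, and their adjusted p-values then, were the syncytiotrophoblast and labyrinth genes (0.102), H3K9 methyltransferases and readers (0.410), H3K9 demethylases (0.259), p53 target genes (0.0699), hypoxia and glycolysis genes (0.287), immediate early genes (0.0825) and WNT target genes (0.0775). Under an estimated correlation but with Rn45s left out, 4 of them had adjusted p-values under 0.05, namely the syncytiotrophoblast (0.0201), p53 (0.0428), hypoxia (0.0428) and WNT (0.0355) lists. With Rn45s left out camera also called the extraembryonic mesoderm and blood progenitor genes (adjusted p = 0.0485, or 0.140 with an estimated correlation, against 0.0806 as deposited). That list had 0.0189 without E6.5 WT replicate 1 and 0.0258 without E7.5 KO replicate 1. The methyltransferases had an adjusted p = 0.0553, 0.0668 and 0.0568 without E6.5 WT replicate 2, E7.5 KO replicate 1 and E7.5 KO replicate 3. Higher values made up 1101 of the calls against 803 with Rn45s left out (57.8%), and 1032 against 986 after quantile normalization (51.1%).

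The comparison of E7.5 with E6.5 in WT gives the change with development as a scale for the KO differences. The intermediate filament gene Vim (chromosome 2, positions 13573927 to 13582826) was 0.16 ± 0.16 at E6.5 and 4.15 ± 0.11 at E7.5 (SD, n = 3), a rise of 3.99 (SE 0.10, adjusted p = 6.8e-11), and the transcription factor Tbx3 rose by 3.65 (SE 0.06). Prtg (3.28), Esx1 (3.17), the fibrillin Fbn2 (3.09), Itga4 (3.04), Acta2 (2.84) and the matrix genes Hapln1 (2.68) and Vcan (2.62) rose with them. Olr1 (-2.95), the placental gene Plac1 (-2.74), Irx1 (-2.74), Fgfbp1 (-2.68), Cebpa (-2.53) and the keratin Krt7 (-2.29) fell. Of the cholesterol synthesis genes, 19 of 19 tested genes fell (19 fell adjusted over the list alone), with Msmo1 (-1.63) and Lss (-1.29). For cholesterol synthesis genes camera gave an adjusted p = 3.7e-07, or an adjusted p = 0.0130 with an estimated correlation. Of the BMP and SMAD target genes, 6 of 9 tested genes rose and 2 fell (6 rose and 3 fell adjusted over the list alone), with Msx2 (2.504), Id3 (2.06) and Id1 (1.77) up. For BMP and SMAD target genes camera gave an adjusted p = 3.9e-05, or an adjusted p = 0.0149 with an estimated correlation; the latter was 0.0524 with Rn45s left out. Of the WNT target genes, 4 of 5 tested genes rose (4 rose adjusted over the list alone), with Nkd1 (1.62) and Axin2 (0.94). For WNT target genes camera gave an adjusted p = 5.4e-05, or an adjusted p = 0.0277 with an estimated correlation. Of the epiblast genes, 8 of 8 tested genes fell (8 fell adjusted over the list alone), with Sox3 (-1.89). For epiblast genes camera gave an adjusted p = 0.00203, or an adjusted p = 0.0344 with an estimated correlation.

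Markers of neighbouring tissue moved with stage in WT as well. Of the visceral endoderm genes, 8 of 12 tested genes rose and 2 fell (8 rose and 2 fell adjusted over the list alone), with Lrp2 (1.57) and Cubn (1.25). For visceral endoderm genes camera gave an adjusted p = 2.2e-05, or an adjusted p = 0.0130 with an estimated correlation; the latter was 0.0508 with Rn45s left out. Of the parietal endoderm genes, 5 of 9 tested genes rose and 2 fell (5 rose and 2 fell adjusted over the list alone). For parietal endoderm genes camera gave an adjusted p = 0.000571, or an adjusted p = 0.0277 with an estimated correlation, and 0.0576 and 0.104 with Rn45s left out. Of the extraembryonic mesoderm and blood progenitor genes, 5 of 10 tested genes rose and 2 fell (5 rose and 2 fell adjusted over the list alone), with Tal1 (1.97) and Lmo2 (1.81) up and Gata1 (-1.21) down. For extraembryonic mesoderm and blood progenitor genes camera gave an adjusted p = 0.00366, or an adjusted p = 0.0781 with an estimated correlation, and 0.106 and 0.212 with Rn45s left out. T fell by 1.40 and Pdgfra rose by 1.89; in all, 2 of 4 tested streak and mesoderm genes rose and 2 fell (2 and 2 adjusted over the list alone). Trophoblast genes mostly fell: of the ExE and trophoblast stem cell genes, 5 of 26 tested genes rose and 18 fell (5 rose and 19 fell adjusted over the list alone), with Elf5 (-1.97) and Rhox9 (2.30) at the ends, and of the ectoplacental cone and spongiotrophoblast genes, 2 of 10 tested genes rose and 8 fell (2 rose and 8 fell adjusted over the list alone), with Nrk (-1.74) and Gjb5 (-1.79), while camera gave adjusted p-values of 0.208 and 0.185. With Rn45s left out camera called both lists lower (adjusted p = 0.00540 and 0.0146, or 0.0298 and 0.0528 with an estimated correlation). Of the syncytiotrophoblast and labyrinth genes, 2 of 11 tested genes rose and 8 fell (2 rose and 8 fell adjusted over the list alone), and camera gave an adjusted p = 0.550. Of the ribosomal protein genes, 73 of 78 tested genes fell (74 fell adjusted over the list alone). For ribosomal protein genes camera gave an adjusted p = 1.1e-12, or an adjusted p = 0.0130 with an estimated correlation. Of the replication-dependent histone genes, 56 of 66 tested genes fell (57 fell adjusted over the list alone). For replication-dependent histone genes camera gave an adjusted p = 6.4e-08, or an adjusted p = 0.0361 with an estimated correlation. With Rn45s, whose share was higher at E7.5, left out, 61 ribosomal protein and 45 histone genes fell (camera adjusted p = 3.4e-18 and 1.8e-13, or 0.01002 and 0.0160 with an estimated correlation), and their medians went from -0.68 and -0.68 to -0.36 and -0.38.

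Camera also called immediate early genes (1 rose and 13 fell of 14, with Egr1 (-1.41) and Fos (-1.37)), hypoxia and glycolysis genes (3 rose and 13 fell of 18, with Ndrg1 (-1.54)), DNA replication genes (17 of 20 fell, with Mcm5 (-0.78)), paternally expressed imprinted genes (10 rose and 7 fell of 21) and Zfp genes (79 rose and 72 fell of 252). Adjusted over the list alone, the counts were 1 and 13, 3 and 13, 17, 10 and 7, and 76 and 71. Their adjusted p-values were 0.00122, 0.0435, 0.0132, 0.000484 and 6.4e-08, but 0.0781, 0.498, 0.276, 0.0920 and 0.0872 with an estimated correlation, and DNA replication had an adjusted p = 0.409 with Rn45s left out. Leaving Rn45s out, 135 Zfp genes rose and 19 fell, and 15 paternally expressed imprinted genes rose and 4 fell; after quantile normalization the counts were 113 and 29, and 15 and 4. Of the DNA replication genes 3 rose and 6 fell under both scalings. With Rn45s left out and an estimated correlation, camera gave the immediate early, hypoxia and paternally expressed imprinted lists adjusted p-values of 0.01002, 0.0260 and 0.0411. The lists not called by camera in WT were FGF and ERK targets (1 rose and 10 fell of 13, adjusted p = 0.294), maternally expressed imprinted genes (3 and 10 of 15, 0.550), mitosis (1 and 13 of 20, 0.323), p53 targets (2 and 6 of 16, 0.613), unfolded protein (9 of 16 fell, 0.323), germline (2 and 7 of 11, 0.711), Rhox (2 and 5 of 13, 0.0582), interferon response (1 and 3 of 5, 0.969), H3K9 methyltransferases and readers (3 and 9 of 21, 0.674), H3K9 demethylases (6 of 10 fell, 0.554), DNA methylation (1 and 9 of 15, 0.773) and Polycomb (1 and 9 of 21, 0.550). Adjusted over the list alone, these counts were 1 and 10, 3 and 11, 1 and 13, 2 and 6, 9, 3 and 7, 2 and 5, 1 and 4, 3 and 8, 6, 1 and 9, and 1 and 8 in the same order. With Rn45s left out camera called the FGF and ERK targets lower (adjusted p = 0.0270, or 0.0877 with an estimated correlation). The medians of the mitosis, DNA replication, p53, interferon, methyltransferase, demethylase, DNA methylation and Polycomb lists changed sign with Rn45s left out. Rises and falls were then 9 and 6 (mitosis), 7 and 4 (p53), 14 and 4 (methyltransferases), 3 and 2 (demethylases), 7 and 5 (DNA methylation) and 12 and 2 (Polycomb), and after quantile normalization 7 and 7, 7 and 4, 11 and 4, 2 and 3, 6 and 5, and 8 and 3. Maternally expressed imprinted genes had 5 and 5 with Rn45s left out and 5 and 6 after quantile normalization, Rhox genes 3 and 3 under both, and unfolded protein genes 2 and 7 with Rn45s left out. Without E7.5 WT replicate 1 camera gave the Rhox genes an adjusted p = 0.0321.

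In all, limma called 6935 genes between stages in WT, 1174 up and 5761 down, and 6461 in KO, 1504 up and 4957 down. By more than 1, 130 rose and 251 fell in WT and 226 rose and 165 fell in KO. Camera called 14 lists in WT and 13 in KO, of which 8 each with an estimated correlation. Rises made up 16.9% in WT and 23.3% in KO as deposited, 59.8% (3375 rose, 2268 fell) and 61.7% (3479 rose, 2161 fell) with Rn45s left out, and 48.7% (2749 rose, 2896 fell) and 46.7% (2694 rose, 3079 fell) after quantile normalization. Relative to the values rescaled without Rn45s, the median of all genes in the deposited ones was shifted by -0.28 in WT and -0.22 in KO. In KO, visceral endoderm genes fell with stage (11 of 12 tested; 11 adjusted over the list alone; median -2.21). For visceral endoderm genes camera gave an adjusted p = 1.6e-06, or an adjusted p = 0.0127 with an estimated correlation.

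Several lists had too few tested genes for a list test. Of 2 tested two-cell stage genes, limma called 0 in both KO comparisons, with 0 at an unadjusted p under 0.05 at E6.5 and 2 at E7.5 (0 and 2 adjusted over the list alone). Of 3 tested Pramel genes it called 0 at E6.5, with 1 at an unadjusted p under 0.05, and 1 rose and 1 fell at E7.5 (1 and 1 adjusted over the list alone). Of 3 tested decidua genes 1 fell at E6.5, and 1 rose and 2 fell at E7.5 (the same numbers adjusted over the list alone), with Acta2 among those that fell. The 1 tested gene of the blood and immune cell list, Cd68, did not pass at E6.5 (1 adjusted over the list alone) and rose at E7.5. The 1 tested clustered protocadherin, Pcdhgc3, rose at E7.5 (1.14). Of the 2 tested Serpinb9 and Serpina3 cluster genes, 1 rose and 1 fell at E6.5 and 1 rose at E7.5. The 1 tested Hox gene was called in neither KO comparison. Prolactin family, placental cathepsin, Psg and Ceacam, olfactory and vomeronasal receptor genes had no tested member, and no mitochondrially encoded protein gene is in the file.

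**Figure D4:**
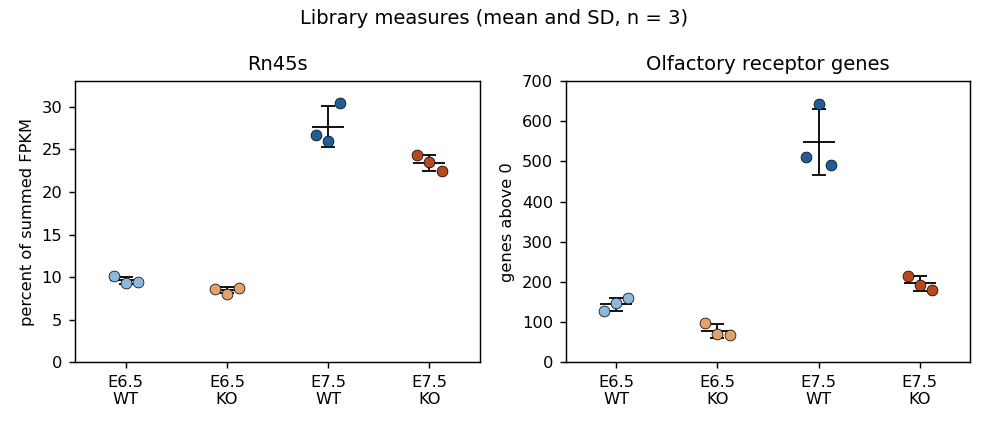
Share of Rn45s in the FPKM total (percent) and number of olfactory receptor genes above 0 (vertical axes) by group (horizontal axes), with 1 point per library, a line at the mean and bars for the SD of the 3. Both are highest in the E7.5 WT libraries, where Rn45s holds 27.7% of the total on average.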

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

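The tests of explanations and the splits of the samples in this part were chosen only after the results were seen; the interaction tests were planned. In the first pattern, visceral endoderm genes were higher in E6.5 KO, where Apob reached 6.54, Cubn 6.44 and Lrp2 5.00. The values argue against a general release of germline and two-cell genes, since 1.92% of 52 had all KO libraries above all WT libraries. They argue against the share of Rn45s too, since the median relative to all genes was 3.20 with Rn45s left out. Of 24 interferon response genes, 10 had all KO libraries above all WT libraries and 0 below. Among all tested genes 34.4% showed no overlap in either direction. The count above WT was 15 of 26 for ExE genes and 0 of 20 for p53 target genes. Of the 5 tested interferon genes, 1 rose with Rn45s left out (camera adjusted p = 0.593). The count therefore decides nothing, and a release of other silenced families stays open. More visceral endoderm cells in the KO libraries stay open, since the labels' dissection names no step that removes this layer, but that 95.5% of the 22 listed genes were separated in that direction only restates the pattern. Visceral endoderm genes switched on within trophoblast cells cannot be told apart from added cells, since the median of ExE genes relative to all genes was 0.083, too near 0 to decide, and no library of pure visceral endoderm is in the series. A direct effect of the KO stays open.

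In the next pattern, epiblast, mesoderm and blood progenitor genes were higher in E7.5 KO, with T at 5.02, Utf1 at 4.76, Pdgfra at 4.16 and Lmo2 at 3.94. The share of Rn45s is argued against by a median of 0.85 relative to all genes with Rn45s left out. Tissue held at an E6.5 state is argued against for the mesoderm and blood progenitor genes, since 93.1% of the 29 that were higher also stood above every E6.5 WT library. More cells of epiblast and mesoderm stay open; the 82.7% of 52 listed genes separated in that direction only restate the pattern. An effect of the KO on these genes within ExE cells was not tested and stays open.

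In the last pattern, genes that fell with stage in WT were higher in E7.5 KO, outside the lists of other cells: with Rn45s left out, 90.4% of 115 genes that fell by over 1, and 84.6% of 26 trophoblast list genes that fell by any size, where the shared WT libraries alone give 56.1% of the former and 56.7% of all tested genes were higher. As deposited it was 91.4% of 245 (70.7% of all tested genes), and after quantile normalization 83.5% of 127 (44.5%). Delayed development would lower the genes that rose with stage. Of 226 that rose by over 1 with Rn45s left out, 46.5% were lower, with 65 called lower and 96 called higher. It was 43.6% of 117 as deposited and 50.0% of 152 after quantile normalization. That argues against delay as the only cause for these genes as a set. A change in the mix of cells could raise some of them and hide a delay, so delay beside such a change stays open. Of 12 trophoblast list genes that rose, 66.7% were lower and 7 called lower, so for trophoblast genes delay and a change in the mix of cells cannot be told apart with so few genes. Across genes with Rn45s left out, the covariance of the KO difference with the stage change was -0.0380, against -0.00683 simulated with unchanged groups. The correlation was -0.25, against -0.49 in that simulation. The simulated groups held no change with stage, unlike the real ones, so the correlations cannot be compared and decide nothing.

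The KO difference differed between stages for 1982 of 10402 tested genes by the test of the interaction. It did so for 143 of the 198 genes the naming rule gives for the KO comparisons, and 61 were over 1 in size. That rule picks large differences at single stages, which favours a called interaction. The higher share among named genes is therefore no result about them. A lower difference at E7.5 was found for Apob -6.34, Cubn -5.60, Cebpb -4.98, Dpp4 -4.80, Lrp2 -3.88, Hnf4a -3.25, Apoa1 -3.23, Dab2 -2.84, Apoa4 -2.76, Lama1 -2.27, Rhox9 -1.91, Rhox6 -1.91, Rhox4d -1.69, Jun -1.60, Col4a1 -1.36, Esx1 -1.28, Itga4 -1.28, Xist -1.27, Gata2 -1.14, Irx4 -1.12, Phf19 -1.11, Pdgfra -1.11, Acta2 -1.11, Gpc3 -1.08, Has2 -1.01, Rhox4b -1.01 and Id3 -1.01. A higher difference was found for Rps13 1.01, Amot 1.01, Kdm5d 1.06, Perp 1.08, Hist1h2ba 1.08, Sox3 1.09, Dynlt1f 1.13, Lmo2 1.17, Rex2 1.20, Kdm7a 1.26, Vldlr 1.27, Pou5f1 1.27, Mest 1.29, Msx1 1.297, Lincenc1 1.32, Eif2s3y 1.32, Pcdhgc3 1.33, Zfp423 1.35, Tdgf1 1.36, Spry4 1.38, Zfp521 1.40, Ddx3y 1.43, Plk2 1.44, Zic3 1.49, Bmp4 1.64, Plac1 1.74, Il17rd 1.83, Armcx4 1.92, Dusp6 2.07, Hbb-bh1 2.14, Rps28 2.16, Foxf1 2.61, Kdr 2.90 and T 3.84, and the targeted gene Suv39h2 had 0.37. The lists whose interaction passed as deposited, with an estimated correlation too, had medians of -2.80 (visceral endoderm genes), -0.80 (parietal endoderm genes), -0.71 (Rhox genes), 0.62 (epiblast genes), 0.75 (FGF and ERK target genes), 0.30 (cholesterol synthesis genes), 0.19 (ribosomal protein genes) and 0.34 (replication-dependent histone genes); with Rn45s left out the ribosomal protein genes had a median of 0.12 and did not pass with an estimated correlation (camera adjusted p = 0.140).

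Some listed genes below the expression filter stood at 1 or more in every KO library of a stage. Every WT library of that stage was under 0.5. Only this direction was searched, so genes at such levels in WT but not in KO were not looked for. Their KO means are given, and these genes were outside the tests. At E6.5 they were the visceral endoderm genes Ttr 1.99, Apom 1.66, Sox17 1.298 and Spink1 2.24 (listed at 0 in WT), the epiblast gene Fgf5 1.16, Igfbp5 1.302 and the adult globin Hba-a2 1.93. At E7.5 they were the epiblast genes Nanog 1.75 and Fgf5 1.19, the streak and mesoderm genes Mixl1 1.73, Mesp1 2.097 and Cdx4 2.51, the allantois gene Tbx4 3.51, Fst 2.04, Hoxb5 1.16, Hoxd1 1.54 and Hoxd9 1.86.

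The 6 libraries of each comparison of 2 groups give 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave 1070 genes and 15 lists for KO against WT at E6.5 (highest other 2 and 7), 4085 and 10 at E7.5 (1 and 4), 6935 and 14 for the stages in WT (1 and 11) and 6461 and 13 in KO (1 and 10). For the interaction, 100 splits within the stages were drawn with the real one. As many genes as the real 1982 came from 4 of the 100 (highest other 2254) and the real 15 lists from 1 of 100 (highest other 10). These splits do not decide, since splits that mix KO and WT put the KO effect into the spread, and the 3 others with as many genes all kept KO and WT apart at E7.5. The same 100 splits were therefore made of the residuals of a fit of genotype and stage without interaction, with that fit kept. As many genes then came from 1 of 100 splits (highest other 2). These residuals still hold the interaction, so splits that mix KO and WT put it into the spread. The real split gave the most genes, but the low counts of the other splits do not by themselves exclude chance. As many lists came from 2 of 100 (highest other 15), a share under 0.05. A chance split equalled the real list count, so chance is not excluded for it.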

How the results depend on the processing

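Leaving out Rn45s, alone or with an estimated correlation, subtracting the olfactory mean, leaving out chromosomes X and Y and the alternatives for single-gene stage and interaction values were chosen after seeing the data; the other alternatives were planned. Of 230 alternative values of the leading results, 204 kept their direction and side of the threshold, or, for counts, stayed within 1.5 times. The exceptions follow, and the cause was not tested. The count of genes at E6.5 (1070) was 2198 with array weights, which gave E6.5 KO replicate 1 a weight of 2.77, and 582 to 845 with a library left out: 625 without E6.5 KO replicate 1, 582 without KO replicate 2, and 665, 662 and 676 without WT replicates 1, 2 and 3. With a library left out, the counts were 3520 to 3863 at E7.5, 6412 to 6661 for stage in WT, 5911 to 6059 in KO and 1584 to 1933 for the interaction. Suv39h2 ranged from -0.44 to -0.34 at E6.5 and from -0.047 to 0.011 at E7.5, the latter without E7.5 WT replicate 2, and was -0.13 after quantile normalization at E7.5 (adjusted p = 0.0494; up to 0.991 with a library left out). Prdm2 ranged from 0.05 to 0.08 at E6.5 and from 0.040 to 0.14 at E7.5, with 0.14 (adjusted p = 0.0169) without E7.5 WT replicate 2 and adjusted p-values up to 0.514.

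The number of lists called was 9, 5, 8, 8 and 8 with an estimated correlation (KO at E6.5, KO at E7.5, stage in WT, stage in KO, interaction). With Rn45s left out too it was 11, 7, 9, 6 and 11. It was 27, 27, 26 and 25 with fry and 25, 28, 25 and 32 with no filter for the last 4. With a library left out it was 14 to 15, 10 to 11, 14 to 15, 12 to 13 and 14 to 16. The overlap of the KO comparisons in the same direction was 1325 genes at unadjusted p under 0.05 at both stages, against 595. Among named genes at E6.5, 227 of 1795 alternative values were no longer past the threshold, in 33 of 107 genes; at E7.5 84 of 2313 were not, and for stage in WT 62 of 2506. Values that changed sign at E7.5 were Kdm5d -0.024 and Uty -0.041 after quantile normalization. For stage in WT they were, after quantile normalization and with Rn45s left out, Eif1a 0.083 and 0.11, Ddx3y 0.069 and 0.11, Pramef12 0.078 and 0.13, Prdm2 0.10 and 0.13 and Xist 0.22 and 0.20, and Bst2 0.0083 with Rn45s left out.

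With the replicate number as a block within each stage, 678 genes were called at E6.5, 3640 at E7.5, 6732 for stage in WT, 6225 in KO and 1558 for the interaction; the numbers do not pair the samples, since deviations of libraries with the same number correlated across genes at -0.01, 0.13 and -0.03 at E6.5 and -0.05, -0.07 and -0.05 at E7.5. Under the block, camera no longer called the syncytiotrophoblast list at E6.5 (adjusted p = 0.0582), hypoxia for stage in WT (0.0917), DNA replication for stage in KO (0.05002) and the H3K9 methyltransferases for the interaction (0.0501). Without E7.5 KO replicate 3 camera gave DNA replication an adjusted p = 0.0525 for stage in KO. With no filter camera did not call the syncytiotrophoblast list (adjusted p = 0.353) or the extraembryonic mesoderm and blood progenitor list (0.0623) at E6.5. Nor did it call the paternally expressed imprinted list for stage in WT (0.0820).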

Other observations

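The groups and genes in this part were picked after their values were seen, and nothing here was planned. The imprinted Dlk1 to Meg3 cluster on chromosome 12 (mm10, positions 109452823 to 109749460) held genes that were higher in KO; it was not tested as a list. At E7.5 limma gave Dlk1 0.94 (adjusted p = 3.7e-05), Meg3 1.12, Rtl1 1.19, Rian 1.19 and Mirg 1.36, with 3 libraries per group; at E6.5 the values were 0.33, 0.69, 0.52, 0.40 and 0.49, and Meg3, Rtl1 and Rian passed while Dlk1 (adjusted p = 0.0782) and Mirg (adjusted p = 0.0580) did not. Dlk1 and Rtl1 are expressed from the paternal copy and Meg3, Rian and Mirg from the maternal copy. Hox genes, which pattern the body axis, are mostly below the filter. Of these, 23 of 39 had all 3 KO libraries above all 3 WT libraries at E7.5 and 3 of 39 at E6.5. Chance gives 5% for a single gene, and 46.9% of all tested genes at E7.5 and 34.4% at E6.5 showed no overlap in either direction. Hoxb6 averaged 2.61 in E7.5 KO and 0.88 in WT, Hoxd9 1.86 and 0.15, Hoxd1 1.54 and 0.39, and Hoxc8 1.303 and 0.42.

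A larger share of X-linked than of autosomal genes differed by more than 1 in each comparison looked at, and the shares were not tested against each other. The sex makeup of the samples was not adjusted for. Xist differed between KO and WT at both stages, and the Y-linked genes differed at E6.5. At E7.5 16 of 342 tested X-linked genes rose and 7 fell by more than 1, 6.73% against 1.76% of 9673 autosomal genes; the shares were 1.46% and 0.496% for KO against WT at E6.5, 7.31% and 3.61% for stage in WT and 7.02% and 1.67% for the interaction. Those that rose include Amot (2.62), Gpc3 (2.63), Armcx4 (2.34), Stard8 (2.06), Tmem47 (1.96), Armcx2 (1.95), Nr0b1 (1.702) and the apelin gene Apln (1.64), and those that fell include 4 Rhox genes (Rhox4b, Rhox4d, Rhox6 and Rhox9) and Esx1 (-1.53). As a group at E7.5, camera called no shift of X-linked genes against the others, with p = 0.965 and, with an estimated correlation, p = 0.986.

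Olfactory receptor genes were above 0 for 145 ± 16.3 of 1125 genes in E6.5 WT (SD, n = 3), 79.0 ± 17.4 in E6.5 KO, 548 ± 82.7 in E7.5 WT and 196 ± 17.9 in E7.5 KO. Of the tested genes, 15 differed by more than 3 log2 units between libraries of 1 group, 6 of them in at least 2 groups, among them Cebpb, Hist1h2ao, Rpl34-ps1, Rpl37rt and Srp54c, against a median range of 0.139 for all tested genes.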
